A study of Mus musculus with 2 samples.

How the data were processed

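Single-cell transcriptomes were measured in 2 libraries of mouse bone marrow progenitors, 1 from wild-type animals (WT) and 1 from animals with LCR1 knocked out (KO). Per the labels' protocols, cells were sorted as viable, CD45-positive, lineage-negative and CD127-positive, with a purity above 90%, from animals of the C57BL/6 strain aged 8 to 12 weeks. The animals of a genotype were pooled, with as many males as females. Libraries were made with the 10x Genomics Chromium 3' chemistry v3.1, which primes on poly(A) tails and reads the 3' end of transcripts with a unique molecular identifier (UMI). The protocols aimed at 10000 cells per library and 20000 read pairs per cell, on a NextSeq or a NovaSeq instrument, and which library ran on which is not given in the sources used here.

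The deposited matrices hold raw UMI counts per gene and barcode, written by Cell Ranger per the file headers (software version 3.1.0) and per the submitters' processing notes, which name the genome build mm10. The same notes name Seurat, whose role for these files is not given in the sources used here, and neither is the gene annotation release. Only barcodes with at least 527 UMIs in WT and 500 in KO are listed, so a cell caller or a minimum had been applied before deposit. The 2 libraries carry different barcode suffixes, as an aggregated run writes them, and whether reads were downsampled there is not given. Both libraries list 31053 genes, of which 19613 in WT and 19839 in KO had a UMI. Because whole counts were deposited, sums of UMIs were used throughout. The counts come from the 3' ends of transcripts, and UMIs from near-identical genes can be lost or split between copies, so levels of genes such as Hspa1a and Hspa1b or the H2 family are less certain.

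Cells were kept with at least 500 genes and at most 10% of UMIs from mitochondrially encoded genes. In WT 12853 barcodes (63.3%) and in KO 6660 (78.6%) reached 500 genes, and the mitochondrial limit then removed 2334 (18.2%) and 2171 (32.6%). The median mitochondrial share over all barcodes was 5.23% in WT and 8.02% in KO. Doublets were sought in each library with Scrublet (in scanpy 1.11.5, expected rate 0.08). It marked 1 WT cell (0.0095%), which counts as a failed call, and the 8% of WT cells with the highest scores (841 cells) were removed instead, while the 47 KO cells that it marked (1.05%) were removed. This left 9678 WT and 4442 KO cells, with 35667561 and 41991312 UMIs.

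Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes were ranked within each library, and the cells of both libraries were clustered together without integration (30 principal components, 15 neighbours, Leiden resolution 1, seed 0), giving 26 clusters. Id2 and its chromosomal neighbours, sex-linked, ribosomal protein and mitochondrial genes were left out of the variable genes. This was done so that the Id2 neighbourhood and the sex of the pooled animals would not define clusters. Clusters were named from 19 marker lists fixed before the data were examined. The rule that turned markers into names was set after seeing the data. A cluster took the name of the list with the highest mean log2 fold over the mean of the other clusters, if that mean was at least 0.5, at least 3 of its markers were 2-fold higher and detected in at least 5% of the cluster's cells, and no other list had as many genes among the 10 leading genes. A cluster whose median UMIs were far under that of its library (3 times lower) needed at least 1 of its markers among those 10. Clusters without a name that carried cycling markers were called cycling. In this way 10 kinds of cell were named, and 6 classes with at least 100 cells in each library were compared.

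Each genotype had 1 library, so no test was run and no p-value is given, and cells were not treated as replicates. Shares of cells are given with exact Clopper-Pearson intervals and UMI sums with exact Poisson intervals, both at 95% and for counting error only. Levels are UMIs of a gene over all UMIs of the class on a counts-per-million scale (CPM). Ratios between libraries were taken on log2(CPM + 5), folds on the CPM values, and intervals of a ratio came from the exact binomial distribution of 1 count given the sum of both. A gene entered the rule of size with at least 50 UMIs over both libraries and 50 CPM in the higher one, and passed it at a 2-fold difference or more with an interval that left out 1. The genes named per class were the up to 12 highest and 12 lowest past that rule, leaving out mitochondrial, ribosomal protein, haemoglobin, immunoglobulin, T cell receptor and sex-linked genes and models without a symbol, together with Id2, its neighbours and up to 4 members of each list with the largest differences. Further genes were named from the lists, and clusters by number, after their values were seen. A few genes that the rule or the lists cover are not reported here.

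Gene lists, 23 in all, were fixed together with the marker lists. For each class the median log2 ratio over the members with at least 20 UMIs was compared with 10000 random lists of the same size, matched on expression in 20 bins, and its percentile describes these libraries only. Members were counted as higher or lower at 1.5-fold. To compare shares of cells with a UMI or with at least 2 cycling markers, each cell was thinned at random to 1500 UMIs and shallower cells were left out. Coordinates came from the GENCODE vM21 annotation of mm10, in which the identifiers of Id2 and its neighbours in the files were all found.

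The rules were tested on data simulated from the class means and depths, with 50 genes changed at each of 4 fold sizes. In ILC2-like cells (2789 genes) the rule recovered 0% of genes at 1.5-fold, 24% at 2-fold, 100% at 3-fold and 100% at 4-fold. In NK or ILC1-like cells (3284 genes) it recovered 2%, 42%, 94% and 100%. None of the unchanged genes passed, and the intervals held the true ratio for 95.2% and 95.5% of genes. Both simulated libraries were drawn from the same class profile with counting error alone. Free RNA, a different mix of cells and variation between animals were left out. These figures therefore do not say how often the rule calls unchanged genes in real libraries. A list that was shifted stood at percentile 100 in both, and 1 of 20 and 1 of 19 other lists lay outside the central 95% of random lists.

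Alternatives chosen at that same time were other limits on genes and mitochondrial share, no doublet removal, Leiden resolutions 0.5 and 2, clusters from thinned cells or from each library alone, a gate on markers per cell, other denominators, TMM factors, a pseudocount of 1 CPM, other UMI minimums and no thinning. Others were added after seeing the data, because many WT barcodes were shallow. They were cells with at least 1000 genes for further results, mitochondrial limits of 5% for the further classes and of 25%, removal of the highest doublet scores in both libraries, and TMM factors and the pseudocount for the other classes. The analysis used Python 3.11.15 with anndata 0.12.19, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9.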

Results

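Single-cell RNA sequencing was performed on bone marrow progenitors of C57BL/6 mice, sorted as viable CD45+ cells that lacked lineage markers and carried CD127, the alpha chain of the interleukin-7 receptor. One library came from wild-type animals (WT) and 1 from animals in which the element called LCR1 had been knocked out (KO). Each library pooled males and females in the same number, aged 8 to 12 weeks, so that each genotype had 1 sample and no difference below has a replicate check. The study asked what the loss of LCR1 does to the development of group 2 innate lymphoid cells (ILC2), tissue-resident lymphocytes that make type 2 cytokines and arise in the marrow from common lymphoid progenitors through an innate lymphoid cell (ILC) precursor. The WT library held 20293 barcodes with 47883132 unique molecular identifiers (UMIs) and a median of 936 UMIs per barcode, and the KO library held 8476 barcodes with 52137780 UMIs and a median of 4078.5. After filtering, 9678 WT cells with a median of 1258 UMIs and 4442 KO cells with a median of 6939 UMIs remained. Of these, 6704 WT cells (69.3%) and 105 KO cells (2.36%) had fewer than 2000 UMIs. Intervals given below are at 95% and cover counting error only.

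Id2, an inhibitor of E protein transcription factors that innate lymphoid cells need for their development, was lower in the KO library in all 3 innate lymphoid classes. In ILC2-like cells it stood at 1007 CPM (UMIs of the gene over all UMIs of the class, on a counts-per-million scale, exact Poisson interval 978 to 1036) in 979 WT cells and at 263 CPM (247 to 281) in 795 KO cells, a 3.82-fold lower level in the KO library (3.56 to 4.10). In ILC precursor-like cells Id2 was 5.09-fold lower in the KO library (4.76 to 5.45), at 1304 against 256 CPM. In cells like natural killer (NK) cells or ILC1 it was 2.15-fold lower (2.00 to 2.32), at 1592 against 739.6 CPM. The gene (ENSMUSG00000020644) lies on the minus strand of chromosome 12 at 25093799 to 25097140 in mm10 and is protein-coding. Where LCR1 lies is not given by the sample labels, so no transcript checks the genotypes directly. That published work on this deletion concerns the Id2 locus is background knowledge and was not checked here.

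The difference in Id2 was also present when every cell was thinned to 1500 UMIs. Of the thinned ILC2-like cells, 64.4% in WT (Clopper-Pearson interval 61.1 to 67.7) and 25.1% in KO (22.1 to 28.3) had an Id2 UMI, against 81.5% and 49.9% without thinning, with 141 WT and 15 KO cells left out as too shallow. The thinned shares were 68.3% and 25.4% in ILC precursor-like cells, where 125 WT and 2 KO cells were left out, against 78.5% and 62.9% without thinning. In NK or ILC1-like cells they were 81.1% and 62.4%, with 2 and 10 cells left out, against 95.2% and 86.6% without thinning. Early B-like cells, which should lack the gene, gave a background of 10.8% in WT and 4.35% in KO, with 320 and 1 cells left out and 15.3% and 17.2% without thinning. Their median depths were 1165 and 11478 UMIs, compared with 4751 and 4306 in ILC2-like cells. In common lymphoid progenitor-like cells the thinned shares, 6.65% and 2.56%, were at or below that background, so no expression is read from them. The level there was 34.8 against 20.8 CPM. Their median depth in WT was 15277 UMIs, so a background from shallower WT cells may be too high, and expression is not excluded.

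**Figure D1:**
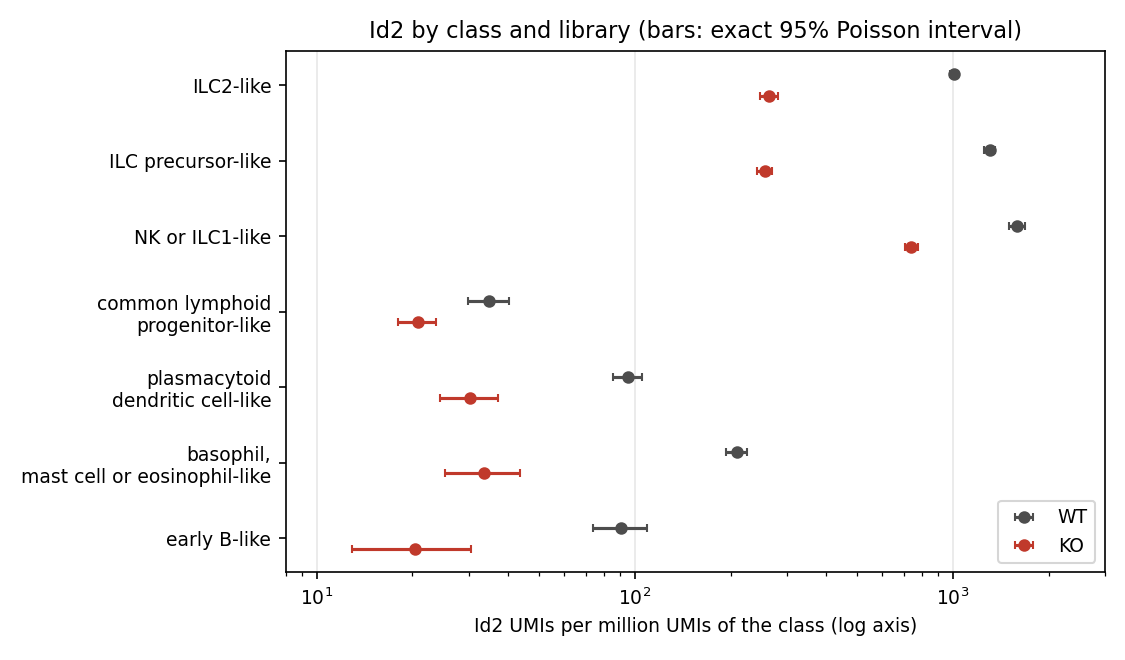
Level of Id2 in each cell class, in CPM of the class on a log axis, for the WT library (grey) and the KO library (red), with exact 95% Poisson intervals as bars. The KO point lies left of the WT point in each class drawn, at 263 against 1007 in ILC2-like cells and 739.6 against 1592 in NK or ILC1-like cells.

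Id2 UMIs in classes outside the innate lymphoid cells were lower in the KO library too, and for the most part could not be separated from RNA of other cells. They stood at 94.9 against 30.3 CPM in plasmacytoid dendritic cell-like cells, 209 against 33.5 CPM in the basophil, mast cell or eosinophil-like class and 90.3 against 20.4 CPM in the early B-like cells used as background. The thinned shares were 12.4% and 7.36% in the first and 26.3% and 7.98% in the second class, with 316 and 1 and with 768 and 3 cells left out. Other ILC2 genes were lower beside Id2, with a median of the ILC2 identity list of -0.97 (15 of 22 genes at least 1.5-fold lower) in the first and -0.89 (14 of 21) in the second. Most WT cells of both lay in shallow clusters. In deep cluster 19 of the first class the thinned shares were 7.63% and 7.42%, at 75.2 and 30.4 CPM. In the second class they were 26.3% and 6.72% in cluster 18, at 227 and 29.2 CPM, a 7.76-fold lower level in KO (5.18 to 12.0). The WT share of cluster 18 (interval 17.9 to 36.1) lay above the early B-like background in WT (6.44 to 16.8). Median depths in cluster 18 were 5063 and 5729.5 UMIs. Whether these cells made Id2 themselves or were doublets was not tested. Cluster 20 of that class gave 8.57% and 11.3%, at 69.9 and 40.5 CPM. The only higher CPM in KO, among named classes and numbered clusters with at least 30 cells in each library, was in cluster 16. This cycling cluster without a lineage name had 37.5 CPM in 52 WT cells and 60.6 CPM in 109 KO cells. The genes beside Id2 differed less in ILC2-like cells. Kidins220, 30.6 kb away, stood at 86.5 and 84.4 CPM, and Ywhaq at 141 and 139.8 CPM. Odc1, 7542 kb away and the enzyme that starts polyamine synthesis, was the neighbour with the widest gap after Id2, at 133 CPM in WT and 232 CPM in KO. The median log2 ratio of KO over WT over the 15 measured genes of this neighbourhood, Id2 included, was -0.04, at percentile 60.9 of random lists of matched expression. The E protein genes Tcf3, Tcf4 and Tcf12, whose products Id2 binds, stood at 35.2 and 32.5, 83.8 and 77.6, and 97.6 and 91.4 CPM in WT and KO, and the 7 measured genes of the list of Id2 and E protein genes had a median of -0.10 (percentile 26.4).

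ILC2-like cells were identified by markers such as Il1rl1, Il2ra and Hs3st1. They made up 979 of 9678 kept cells in WT (10.1%, 9.52 to 10.7) and 795 of 4442 in KO (17.9%, 16.8 to 19.1). This share was 1.77 times higher in the KO library, and its direction changed with the limit on genes, the denominator and other settings. Among the kept cells with at least 1000 genes, ILC2-like cells were 777 of 3141 in WT (24.7%, 23.2 to 26.3) and 758 of 4296 in KO (17.6%, 16.5 to 18.8), 0.713 times the WT share. Applying that limit to the first clusters was chosen after seeing the data. The same limit with cells clustered again was chosen before and also gave a lower share in KO. Per common lymphoid progenitor-like cell there were 2.92 ILC2-like cells in WT and 1.12 in KO. No direction is therefore read for the ILC2-like share. The sort on CD127 and lineage markers sets all of these shares, which say nothing about cells per animal.

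As named, the earlier lymphoid and the NK or ILC1-like classes took a larger share of the KO library under both limits. The unnamed cluster 0, described below, is left out of them. Common lymphoid progenitor-like cells were 3.46% of kept cells in WT (3.11 to 3.84) and 15.9% in KO (14.8 to 17.0), and 10.5% against 16.4% among cells with at least 1000 genes. ILC precursor-like cells, marked by Zbtb16, Tcf7 and Tox2, were 3.21% in WT (2.87 to 3.58) and 9.10% in KO (8.27 to 9.98), and 4.93% against 9.36% at 1000 genes. NK or ILC1-like cells, marked by Ncr1 and Klrb1c, were 1.28% in WT (1.07 to 1.53) and 10.9% in KO (10.0 to 11.9), and 3.79% against 11.0% at 1000 genes. Basophil, mast cell or eosinophil-like cells were 11.8% in WT (11.2 to 12.5) and 4.30% in KO (3.72 to 4.94), and 9.14% against 4.19% at 1000 genes. Plasmacytoid dendritic cell-like cells were 6.86% and 5.83%, and 9.77% against 5.98% at 1000 genes. The smaller classes in WT and KO were early B-like (4.93% and 2.09%), neutrophil or granulocyte precursor-like (2.74% and 0.090%), erythroid-like (0.909% and 0.855%) and plasma cell-like cells (0.692% and 0.158%), with 31.9% and 24.1% of cells without a name and 22.0% and 8.73% in cycling clusters without a lineage name.

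Several clusters came almost wholly from shallow WT barcodes, and such a cluster may be that library and not a cell type. The ILC precursor-like class joined cluster 8 (120 WT and 403 KO cells) with cluster 12 (191 and 1), so that most of its WT cells lay in cluster 12, at a median of 1243 UMIs. Cluster 11 held 970 WT and 2 KO basophil-like cells, while most KO cells of that class lay in cluster 18. Cluster 2 held 415 WT and 3 KO plasmacytoid dendritic cell-like cells, while most KO cells of that class lay in cluster 19, and cluster 10 held 449 of the WT and 1 of the KO early B-like cells, most KO cells lying in cluster 25. When only cells with at most 5% mitochondrial UMIs were clustered, an alternative added after seeing the data, the cluster called common lymphoid progenitor-like took 1055 WT and 12 KO cells, and the common lymphoid progenitor-like share, KO over WT, was 0.0257 in place of 4.60.

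**Figure D2:**
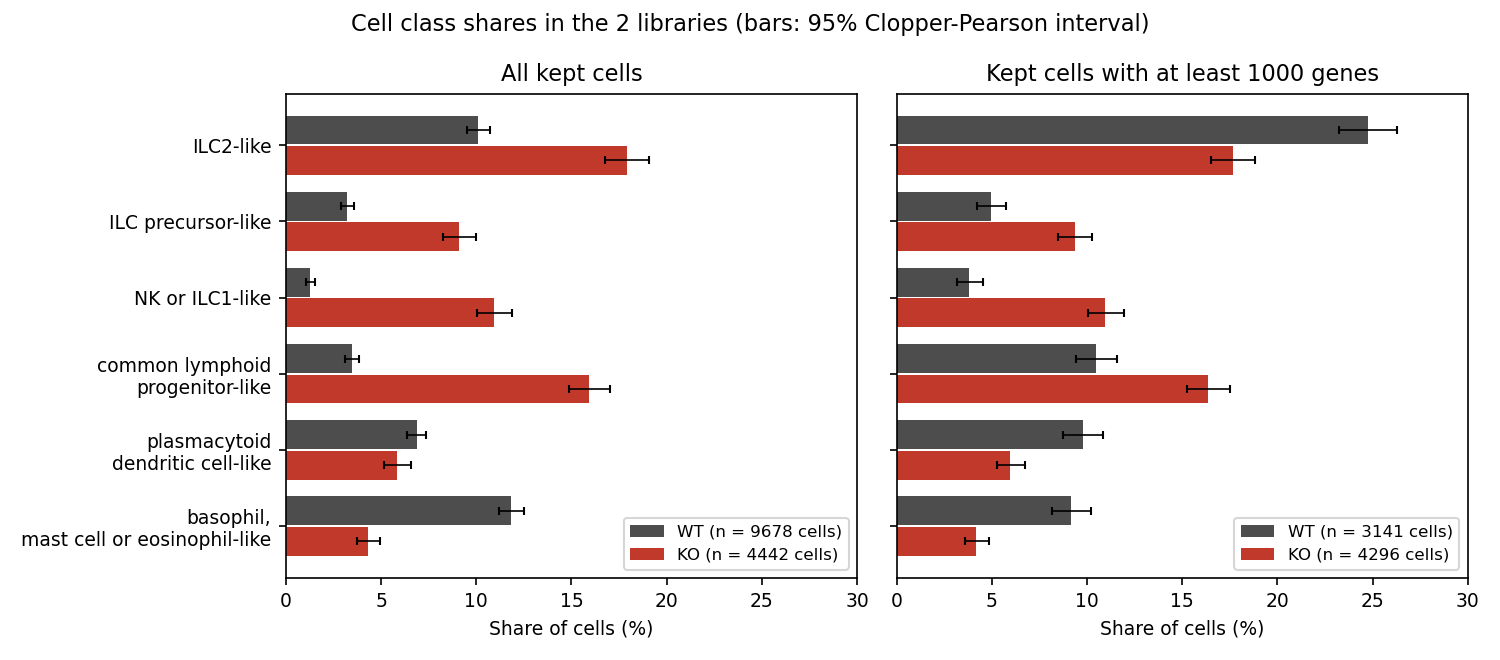
Share of cells in each of the 6 compared classes, in percent, for the WT library (grey) and the KO library (red), over all kept cells (left) and over kept cells with at least 1000 genes (right), with 95% Clopper-Pearson intervals as bars. The ILC2-like share is higher in KO on the left, at 17.9% against 10.1%, and lower on the right, at 17.6% against 24.7%, while the ILC precursor-like, NK or ILC1-like and common lymphoid progenitor-like shares are higher in KO in both.

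Within ILC2-like cells, Id2 had the largest fold among the genes lower in the KO library that the naming rule admits, and a few genes were higher. Cxcl10, an interferon-inducible chemokine, stood at 12.0 CPM in WT and 78.5 CPM in KO, 6.52-fold higher (4.87 to 8.87). Cxcl10 was also a leading gene of the unnamed cluster 23, with 28 WT and 380 KO cells. Whether RNA of those cells adds to its level here was not tested. Il18r1, a chain of the interleukin-18 receptor that early ILC2 and ILC precursors carry, was 2.63-fold higher at 31.3 and 82.4 CPM, and Rgs2, a regulator of G protein signalling, 2.53-fold higher at 143 and 360.1 CPM. Tnfaip3, a brake on NF-kappaB signalling, stood at 183 and 376 CPM, Rel, an NF-kappaB subunit, at 25.8 and 61.1 CPM, and Tiparp, a target of the aryl hydrocarbon receptor, at 19.0 and 51.6 CPM. Beside Id2, the basophil protease gene Prss34 was 2.39-fold lower in KO, at 133 and 55.8 CPM. Of 2886 genes measured well enough for the rule of size, 8 were higher and 5 lower in the KO library. When ILC2-like cells were chosen by markers per cell, only Cxcl10 of the 6 higher genes named here still passed the rule. In thinned cells Cxcl10, Rgs2 and Rel did. Id2 and Prss34 passed it in both. The remaining 5 were 2 gene models without a name, the immunoglobulin genes Igkc and Igha and the haemoglobin gene Hba-a1. In simulated data for these cells the rule found 24% of genes with a 2-fold difference and 100% of those with a 3-fold difference, so differences near 2-fold were often below its reach.

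**Figure D3:**
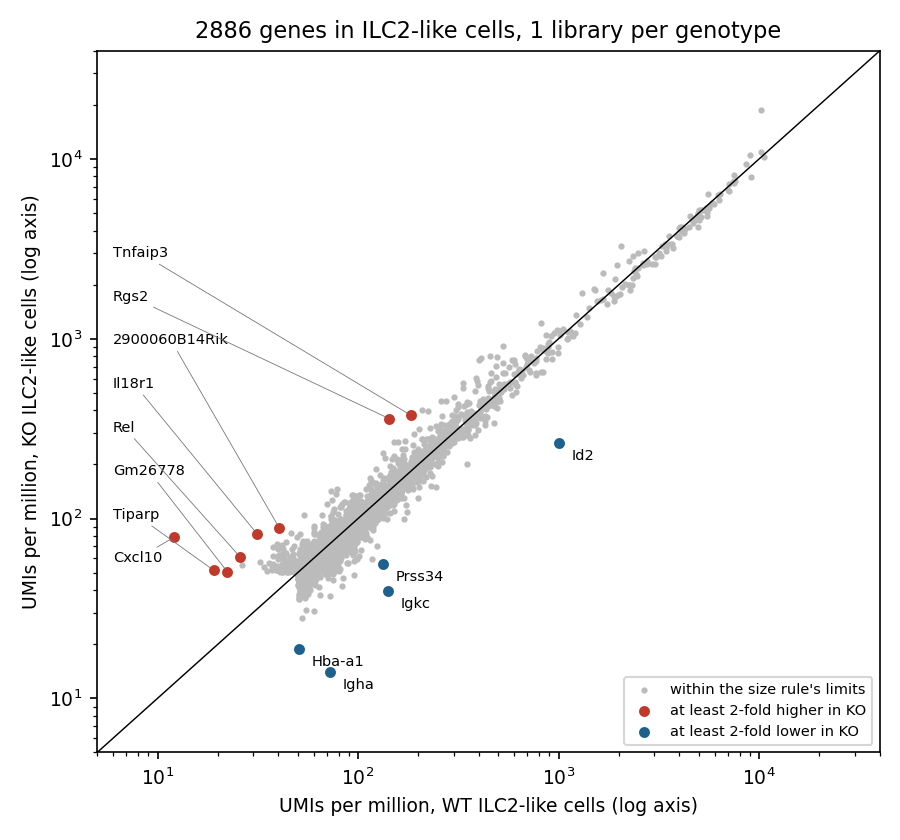
Level of each of 2886 genes in ILC2-like cells, in CPM of the class, in WT (x axis) and KO (y axis) on log axes, with 1 library per genotype and a line of equal levels. The 8 genes past the rule of size and higher in KO are red and the 5 lower in KO are blue, with Id2 far below the line at 1007 in WT and 263 in KO.

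Genes that define ILC2 were largely present in both libraries, which naming the class by ILC2 markers in joint clusters made likely in advance. The ILC2 identity list, which shares genes with the markers used to name the class, had a median log2 ratio of KO over WT of -0.16 over 28 measured genes, below 99% of random lists (percentile 0.02), while its mean was 0.03. Of the 28, 3 were at least 1.5-fold higher in KO, Ccr8, Icos (455 and 799 CPM) and Tcf7 (20.6 and 35.9 CPM), and 0 were lower by that much. Rora, a transcription factor that ILC2 need, stood at 816 and 1220.5 CPM, and Il1rl1, the receptor for interleukin-33, at 613 and 504 CPM. Type 2 effector genes had a median of 0.19 (12 genes, percentile 99.8), with Areg, the growth factor amphiregulin, at 15.8 and 25.8 CPM and Il4 at 23.4 and 14.6 CPM. That median was -0.13 when cells were chosen by markers per cell in place of clusters. Genes of the ILC precursor were higher in KO on balance (median 0.16, 17 genes, percentile 99.95), with 4 members higher, among them Cd7 (6.79 and 24.7 CPM) and Nfil3 (14.4 and 29.7 CPM), and 1 lower, Itga4 (350.0 and 200.1 CPM). Lists of some other lymphocytes also had medians above 0, unlike the B lineage and lymphoid progenitor lists given below. The medians were 0.38 for NK and ILC1 effector genes (11 genes, percentile 100), with Il2rb at 39.4 and 72.0 CPM, 0.23 for T lineage genes (10 genes, percentile 99.96) and 0.26 for ILC3 genes (4 genes, percentile 98.3). Cells with such genes were commoner in the KO library, at 1.28% and 10.9% for NK or ILC1-like cells. Unnamed cluster 21, with NK and T cell genes, was 1.01% and 6.28%. Unnamed cluster 23, with ILC3 markers, was 0.289% and 8.55%. RNA of those cells, and doublets with them, are not separated here.

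Immediate early and stress genes were higher in KO ILC2-like cells as a group, with a median of 0.50 over 24 genes (percentile 100) and 9 members at least 1.5-fold higher. Dusp1 stood at 402 and 766 CPM, Klf4 at 209 and 400.2 CPM, Btg2 at 531 and 909 CPM and Fos at 2051 and 3278 CPM. Cell cycle genes had a median of -0.33 (25 genes, percentile 0), with only Kif11 (8.32 and 3.36 CPM) and Stmn1 at least 1.5-fold lower. The cell cycle median in ILC2-like cells was -0.06 when cells were chosen by markers and -0.14 when cells with at least 1000 genes were clustered again. The thinned shares of cycling cells, 13.0% and 11.5%, did not differ beyond counting error. RNA of erythroid and granulocytic cells, which ILC2 should not make, was lower in KO by a median of -1.11 over 8 genes, 7 of them by at least 1.5-fold, with Mpo at 25.8 and 5.33 CPM. B lineage genes had a median of -0.24 (12 genes, percentile 2.17), with Ly6d at 41.2 and 13.7 CPM, glycolysis genes -0.17 (15 genes, percentile 2.40), with Ldha at 840.2 and 649.6 CPM, and ribosomal protein genes -0.07 (80 genes, percentile 0.04). The other lists lay within the central 95% of random lists. Their medians were -0.00 for interleukin-7 and STAT5 response genes (15 genes, percentile 70.5), 0.06 for apoptosis and survival genes (15, 96.3), -0.16 for interferon response genes (23, 3.90) and -0.09 for antigen presentation genes (14, 20.8). They were -0.02 for oxidative phosphorylation genes (29, 41.6), -0.10 for lipid and arginine metabolism genes (14, 29.5), 0.04 for homing and adhesion genes (18, 89.7), -0.12 for lymphoid progenitor genes (18, 12.7) and 0.12 for mitochondrially encoded genes (13, 97.1). The means of the antigen presentation list, at 0.02, and of the interleukin-7 and STAT5 list, at 0.03, had the opposite sign to their medians. With TMM factors in place of class totals, the medians of the interleukin-7 and STAT5, oxidative phosphorylation and Id2 neighbourhood lists lay above 0, as did that of the lymphoid progenitor list when cells with at least 1000 genes were clustered again.

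**Figure D4:**
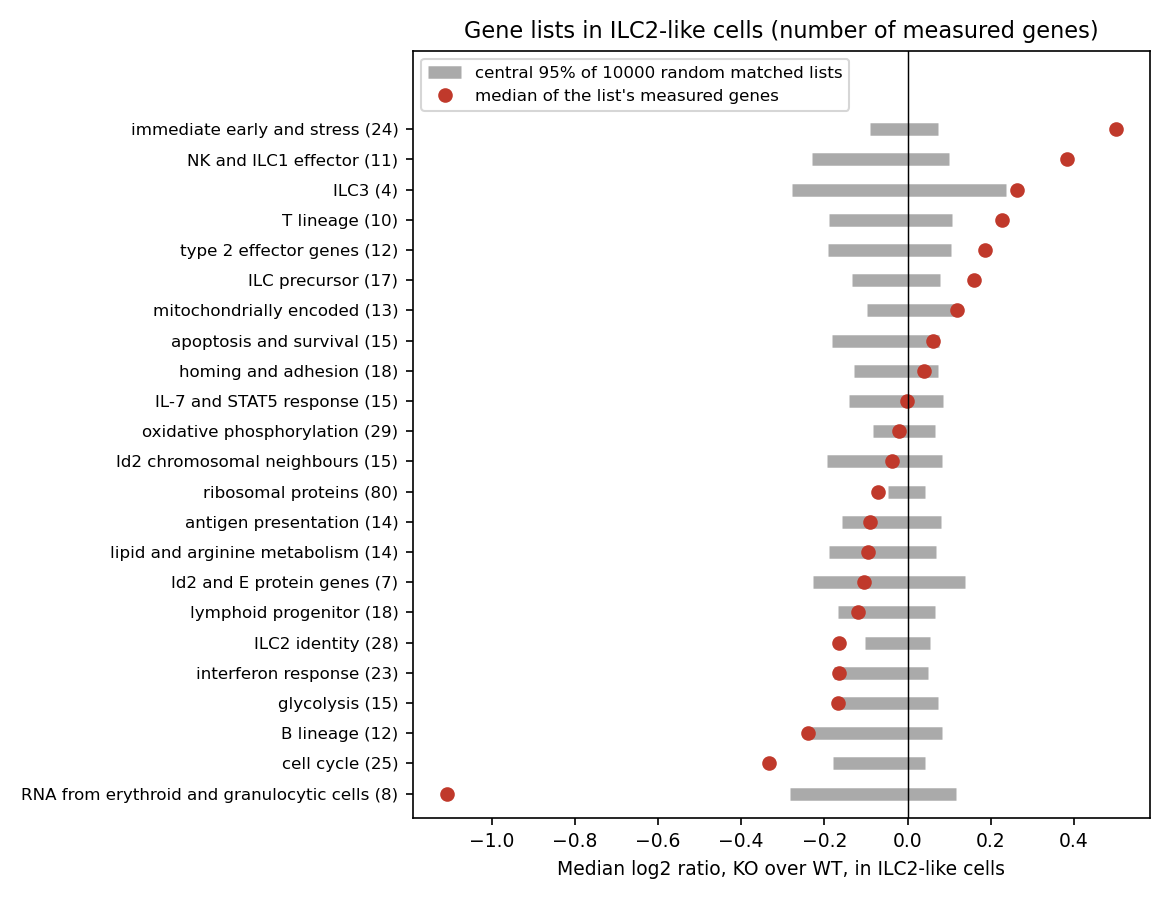
Median log2 ratio of KO over WT over the measured genes of each of 23 gene lists in ILC2-like cells (red points; number of measured genes in brackets), with grey bars for the central 95% of 10000 random lists matched on expression. Immediate early and stress genes lie furthest to the right, at 0.50, and RNA of erythroid and granulocytic cells furthest to the left, at -1.11.

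ILC precursor-like cells of the KO library had lower levels of several ILC2 genes beside Id2 and higher levels of T lineage genes. Stab2 was 5.00-fold lower (54.6 and 10.9 CPM), Bcas1 4.22-fold lower (180.0 and 42.6 CPM), Arg1, which encodes an arginase made by ILC2, 2.47-fold lower (111 and 45.0 CPM) and Tiam1 2.41-fold lower (189 and 78.7 CPM). The ILC2 identity list had a median of -0.37 over 23 measured genes (percentile 0), with 8 members at least 1.5-fold lower, among them Lmo4 (2444 and 1354 CPM) and Il17rb, a chain of the interleukin-25 receptor (68.9 and 37.9 CPM), and 1 higher, Bcl11b (231 and 387 CPM). This list was lower still in the plasmacytoid dendritic cell-like (-0.97) and basophil, mast cell or eosinophil-like (-0.89) classes, which are not innate lymphoid. Not all of its genes are particular to ILC2, and Ccr9 is also on the marker list of plasmacytoid dendritic cells. RNA of erythroid and granulocytic cells had a median of -1.23 (3 genes, percentile 0), with 2 of them at least 1.5-fold lower, and 191 of the 311 WT cells lay in shallow cluster 12, so RNA of other cells is not separated here. The ILC precursor list had a median of -0.22 (19 genes, percentile 0), with Tox2 at 325 and 186 CPM and Pdcd1 at 200.4 and 131 CPM. T lineage genes had a median of 0.48 (15 genes, percentile 100), with 7 members higher and 0 lower, among them Lck, a kinase of T cell receptor signalling (120 and 198 CPM), and Themis (48.6 and 82.7 CPM). Unnamed cluster 21, which carried T cell genes, was commoner in KO (1.01% and 6.28%), and RNA of its cells is not separated here. Arpp21 was 3.31-fold higher (51.6 and 171 CPM), Fam169b 3.48-fold (27.3 and 94.9 CPM), H2-Aa 2.81-fold (26.8 and 75.3 CPM) and Cd74, the invariant chain of class II antigen presentation, 2.23-fold (96.2 and 214 CPM). The antigen presentation list as a whole had a median of -0.05 (15 genes, percentile 19.5) and a mean of 0.27. Of its members 4 were higher, the class II genes H2-Aa, Cd74, H2-Ab1 and H2-Eb1, and 0 lower. All 4 were also leading genes of the unnamed cluster 23, with 28 WT and 380 KO cells, and RNA of those cells is not separated here. B lineage genes had a median of 0.30 (14 genes, percentile 99.98). Type 2 effector genes had -0.30 (6 genes, percentile 0.20), which was 0.0810 when cells with at least 1000 genes were clustered again. Of 3317 genes in the rule, 13 were higher and 14 lower. The basophil gene Mcpt8 was lower too (90.8 and 28.5 CPM), and whether it came from the nearly all-WT cluster 12 was not tested. When cells with at least 1000 genes were clustered again, 27 genes were higher and Ccl4, here 4.26-fold lower, had a log2 ratio of 1.74.

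In common lymphoid progenitor-like cells, the class before commitment to innate lymphoid fate, Hes1 had the largest fold among the genes higher in the KO library that the naming rule admits. Hes1, a target of Notch signalling, stood at 26.8 CPM in WT and 200 CPM in KO, 7.47-fold higher (6.30 to 8.91). Nr4a1 was 6.64-fold higher (9.86 and 65.5 CPM), Gadd45b 4.37-fold (13.0 and 56.9 CPM), Ccl4 3.24-fold (19.3 and 62.6 CPM) and Fos 2.67-fold (532 and 1421 CPM), and Junb, Kdm6b, Zfp36, Dusp2, Ier3, Nfkbiz and Dusp1 were 2.17-fold to 2.57-fold higher. Pclaf, a gene of DNA replication, was 2.16-fold lower (154 and 71.2 CPM), and the cell cycle list had a median of -0.31 over 31 genes (percentile 0), with 7 members lower and 0 higher. B lineage genes had a median of 0.18 (20 genes, percentile 100), with Ebf1, a transcription factor that starts the B lineage, at 124 and 180.0 CPM and 0 members past 1.5-fold either way. The ILC precursor list had a median of -0.26 (15 genes, percentile 0.02), with Tcf7 at 10.6 and 1.80 CPM and Gata3 at 22.5 and 8.39 CPM. The ILC2 identity list, which holds these 2 genes as well, had a median of -0.17 (20 genes, percentile 0.25), with 3 members lower and 0 higher, the other being Il1rl1 (9.30 and 2.30 CPM). The ILC2 identity median in common lymphoid progenitor-like cells was -0.02 when cells with at least 1000 genes were clustered again. Tcf7, Gata3 and Il1rl1 were low in this class, and RNA of other cells is not separated at such levels. The basophil gene Prss34 was lower too, while the list of RNA of erythroid and granulocytic cells differed little (-0.09). Type 2 effector genes had a median of 0.42 (6 genes, percentile 100), with Cxcl2, Tnf and Nfkbia higher and 0 lower, which are genes of the NF-kappaB response and not type 2 cytokines. Medians were also below the central 95% of random lists for lymphoid progenitor (-0.12), interferon response (-0.14), glycolysis (-0.15) and oxidative phosphorylation genes (-0.08). Of 3202 genes in the rule, 14 were higher and 3 lower in KO, Prss34 (57.8 and 21.4 CPM) among the latter.

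NK or ILC1-like cells, 124 in WT and 486 in KO, showed higher Ifng and Socs3 and lower Id2 and Ccl4 in the KO library. Ifng, the cytokine interferon-gamma, stood at 39.0 and 92.2 CPM (2.36-fold higher), Socs3, an inhibitor of cytokine signalling, at 22.9 and 58.4 CPM, Fosl2 at 44.4 and 120.3 CPM and Ier5l at 9.42 and 59.7 CPM. Ccl4 was 3.44-fold lower at 74.0 and 21.5 CPM, and Psmd6, Brd1 and Tufm were 2.41-fold, 2.36-fold and 2.44-fold lower. The NK and ILC1 effector list had a median of -0.12 over 22 genes (percentile 1.98) and a mean of 0.06, with Ncr1, an activating receptor of NK cells, at 642 and 444 CPM and Tbx21, the transcription factor T-bet, at 108 and 77.7 CPM. Antigen presentation genes had a median of -0.26 (15 genes, percentile 0), with Cd74 at 689 and 468 CPM. Of 3381 genes in the rule, 11 were higher and 8 lower in KO, on 743037 WT and 2276755 KO UMIs.

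In plasmacytoid dendritic cell-like cells the immediate early genes Fos (733 and 1629.9 CPM) and Zfp36 (132 and 313 CPM) were higher in the KO library, with Gadd45b (32.0 and 91.9 CPM) and Dusp2 (101 and 215 CPM). The ILC2 identity list (median -0.97), the ILC precursor list (-0.61, 10 of 18 genes at least 1.5-fold lower) and RNA of erythroid and granulocytic cells (-1.20, 6 of 7) were lower, while the B lineage (1 of 18 genes lower) and lymphoid progenitor lists (percentile 24.8) lay within the central 95% of random lists. Genes past the rule as lower included S100a8 of neutrophils (188 UMIs in WT and 0 in KO), the ILC2 genes Gata3 (79.6 and 7.49 CPM) and Rora (56.2 and 13.0 CPM) and the basophil genes Prss34 (173 and 24.1 CPM) and Mcpt8 (122 and 27.4 CPM). In the basophil, mast cell or eosinophil-like class, Prg2, which encodes a granule protein of eosinophils, had 6 UMIs in WT and 143 in KO (1.85 and 87.1 CPM). The chemokine gene Ccl4 was 4.47-fold higher (138 and 617.9 CPM), and Ier3, Osm, Egr1, Rgs1 and Jun were 2.28-fold to 3.25-fold higher. Ccl4 was a leading gene of cluster 18, which gave 723131 of 3236795 UMIs of the class in WT and 958093 of 1641100 in KO. Whether the mix of clusters brought these differences was not tested. In that class the lymphoid progenitor (median -0.81, 10 of 19 genes lower) and B lineage lists (-0.74, 10 of 17) were lower, the latter at 0.0896 when cells with at least 1000 genes were clustered again, and the ILC precursor list lay within random lists (percentile 55.0). Genes past the rule as lower included the lymphoid gene Ly6d (278 and 9.75 CPM), Dntt, the polymerase of antigen receptor joining (356 and 29.9 CPM), and the plasmacytoid dendritic cell gene Siglech (59.3 and 1.83 CPM). The rule counted 4 genes higher and 14 lower among 3382 in the former class, and 18 higher and 46 lower among 3366 in the latter. The shallow WT clusters 2 and 11 weigh on these counts, and among cells with at least 1000 genes clustered again they were 9 higher and 5 lower, and 21 higher and 13 lower.

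Immediate early and stress genes were higher in the KO library in all 6 compared classes. Their median log2 ratio was 0.50 in ILC2-like, 0.55 in NK or ILC1-like, 0.56 in ILC precursor-like, 0.57 in plasmacytoid dendritic cell-like and 0.86 in both the basophil, mast cell or eosinophil-like and the common lymphoid progenitor-like class, each at percentile 100, with 9 to 17 members at least 1.5-fold higher. Fos passed the rule of size in 3 classes. Id2 passed it as lower in 5 classes and, at 34.8 and 20.8 CPM, was below the minimum level in common lymphoid progenitor-like cells. The immunoglobulin gene Igkc was lower in all 6 classes, Igha and Prss34 in 4, and Calca and Ly6a in 3. The source of these transcripts was not tested.

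Fewer common lymphoid progenitor-like cells of the KO library showed cycling markers. At 1500 UMIs per cell, 45.9% of WT (40.5 to 51.5) and 25.6% of KO cells (22.4 to 29.0) had at least 2 of the cycling markers, with 4 cells left out in each, against 90.7% and 87.7% without thinning. In ILC precursor-like cells the shares were 34.4% and 20.4%, with 125 and 2 cells left out, but 61.1% and 73.5% without thinning, and the cell cycle list had a median of 0.12 in that class (percentile 99.2), so no order is read there. In ILC2-like cells the thinned shares, 13.0% and 11.5%, lay within each other's counting intervals, with 141 and 15 cells left out (46.5% and 38.7% without thinning). The same held for NK or ILC1-like cells, at 21.3% and 19.1%, with 2 and 10 left out (54.8% and 51.0%). Basophil, mast cell or eosinophil-like cells gave 74.3% and 49.5%, with 768 and 3 left out (79.6% and 78.0%), and plasmacytoid dendritic cell-like cells 54.6% and 47.3%, with 316 and 1 left out (73.2% and 89.6%). Free RNA of cycling cells can add such UMIs to shallow barcodes, so the shares of the last 2 classes and of ILC precursor-like cells, with many shallow WT barcodes, leave open how many cells were cycling. Common lymphoid progenitor-like cells were deep in both libraries, at a median of 15277 UMIs in WT and 13303 in KO. The list of RNA of erythroid and granulocytic cells differed little there (-0.09 over 5 genes, percentile 23.8).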

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

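Of the tests below, those of free RNA behind the Id2 difference, of depth, of handling and of the LCR1 deletion were chosen only after the result was seen, and those of shallow WT barcodes and of damaged cells before.

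Id2 was lower in the KO library in ILC2-like, ILC precursor-like and NK or ILC1-like cells. Free RNA in the WT library would bring the abundant transcripts of the other lineages with it. The excess of 57 such markers in WT reached at most 2.00% of the level needed (ILC2-like, with 0.661% and 0.730% in the other classes). That result was fixed in advance. The level needed, at least 19998 CPM, exceeds the 10230 CPM of these markers in WT barcodes under 500 genes. Those barcodes held Id2 at 380.3 CPM, against 1007, 1304 and 1592 CPM in the 3 WT classes. Free RNA of that make-up could not reach these levels, which argues against it as the whole cause. At 1500 UMIs per cell the WT share stayed above the KO share in each of the 3 classes. The lower WT limit lay at least 6.30 percentage points above the upper KO limit, which argues against a depth difference as well. An action of the LCR1 deletion on Id2 stays open, and that 0.0693% of the genes in the rule in ILC2-like cells had a log2 ratio at or below that of Id2 restates the pattern and does not support it. With 1 library per genotype it cannot be told apart from another difference between the 2 pools of animals, and a further KO library prepared beside WT would decide.

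The ILC2-like share was higher in the KO library over all kept cells and lower among cells with at least 1000 genes. Shallow WT barcodes may hold free RNA of several lineages. At 500 UMIs per barcode, 4.60% of 6537 kept WT barcodes under 1000 genes had markers of at least 3 of 5 unrelated lineages. Of 3141 above, 1.97% did (ratio 2.33), as free RNA would give. In KO the shares were 0.685% of 146 and 0.396% of 4296 barcodes, so WT barcodes above 1000 genes also exceeded those of KO. The test does not say how many of these barcodes held no cell. Nor does it set apart the barcodes' own lineages, and shallow WT clusters held many basophil-like and early B-like cells. Whether the LCR1 deletion itself alters the ILC2-like share cannot be told apart from other differences between the 2 libraries, with 1 library per genotype. Under 7 of 16 settings the ratio of KO over WT lay below 1, with a range from 0.385 to 3.72.

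Immediate early and stress genes were higher in the KO library in each of the 6 compared classes. Damaged cells with a high mitochondrial share could bring them, but within the KO library cells above the class median of mitochondrial share held more of these UMIs in 3 of the 6 classes, with a ratio from 1.17 in NK or ILC1-like cells down to 0.724 in the basophil, mast cell or eosinophil-like class, which leaves it open. Handling or library preparation of the KO sample would act on cells of every lineage, and the list stood above the random lists in 6 classes. The LCR1 deletion would need the same in each further KO library, and the lowest median over the classes was 0.50. The values given for handling and for the deletion restate the pattern and support neither. These last explanations cannot be told apart, because each genotype was prepared as 1 library.

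The same list was also higher in KO in barcodes that the comparisons do not use, at 12132.5 CPM in KO and 8870.5 CPM in WT among barcodes with at least 500 genes and over 10% mitochondrial UMIs, a ratio of 1.37. Among barcodes under 500 genes the ratio was 0.839.

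The rule of size was passed by 3 genes in opposite directions in different classes, and the differences between classes were not tested. The log2 ratio of KO over WT of Arpp21, a gene of lymphoid progenitors, was -2.41 in basophil, mast cell or eosinophil-like and 1.64 in ILC precursor-like cells. That of the chemokine gene Ccl4 was 2.12 in basophil, mast cell or eosinophil-like and 1.47 in common lymphoid progenitor-like cells, but -1.78 in ILC precursor-like and -1.58 in NK or ILC1-like cells, and in ILC precursor-like cells it was 1.74 when cells with at least 1000 genes were clustered again. In the basophil, mast cell or eosinophil-like class, cluster 18, with Ccl4 among its leading genes, weighed more in KO than in WT. The log2 ratio of Cd74 was -2.82 in basophil, mast cell or eosinophil-like and 1.12 in ILC precursor-like cells.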

How the results depend on the processing

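No paired analysis was possible because each genotype has 1 library, and for the same reason no replicate could be left out. Of 1437 recomputed values, 1153 stayed within a limit, 249 moved beyond it and 27 changed direction. A further 6 counts of genes were more than 1.5 times higher and 2 lower. The limit was the counting interval, or 1.5 times for counts of genes. For list medians it was a width taken from the range of random lists. Of the values that stayed, TMM factors gave 228 chosen before and 86 added after seeing the data. A pseudocount of 1 CPM gave 225 and 97. Both settings reuse the UMI sums of the main values, so the total says little about the other settings. Id2 stayed lower in KO under each setting run for it, in ILC2-like, ILC precursor-like and NK or ILC1-like cells. At resolution 0.5 and at 200 genes no cluster was named common lymphoid progenitor-like, so those settings gave no share for it. The cause was not tested for the differences below. Chosen after seeing the data were cells with at least 1000 genes in the first clusters, the same limit clustered again for results other than shares and Id2, at most 25% mitochondrial UMIs, at most 5% (other than for ILC2-like cells), the highest doublet scores removed in both libraries, and TMM factors and a pseudocount of 1 CPM for some further results.

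The ILC2-like share, KO over WT, was 1.77 and lay below 1 with common lymphoid progenitor-like cells as denominator (0.385), at 1000 genes with the first clusters (0.713) or clustered again (0.711), at 200 genes (0.911), at 25% mitochondrial (0.876), at resolution 2 (0.940) and with clusters from thinned cells (0.990). It was 1.13 with Id2 and its neighbours kept in, 3.72 with each library clustered alone, 2.43 at resolution 0.5, 1.54 at 5% mitochondrial and 1.48 with the highest doublet scores removed in both. The ILC precursor-like share, KO over WT, main value 2.83, was 1.90 and 2.01 at 1000 genes (first clusters and clustered again), 6.62 and 7.43 at 25% and 5% mitochondrial, and 7.22 and 1.52 at resolutions 0.5 and 2. The NK or ILC1-like share, KO over WT, main value 8.54, was 2.89 and 2.90 at 1000 genes, 11.8 at 200 genes, 3.05 with thinned clusters, and 5.53 and 2.13 at resolutions 0.5 and 2. The common lymphoid progenitor-like share, KO over WT, main value 4.60, was 1.56 and 1.78 at 1000 genes, 2.16 with thinned clusters, 6.33 at resolution 2 and 0.0257 at 5% mitochondrial (1055 WT and 12 KO cells so named).

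Id2 in ILC2-like cells, log2 KO over WT, was -1.91, with a range over the settings from -1.99 to -1.71, and was -1.71 with the marker gate, -1.79 as a mean over cells and -1.81 at 25% mitochondrial. Id2 in ILC precursor-like cells, log2 KO over WT, was -2.33, with a range from -2.38 to -2.18, and was -2.20 at 1000 genes, -2.18 as a mean over cells and -2.21 without doublet removal. Id2 in NK or ILC1-like cells, log2 KO over WT, ranged from -1.11 to -1.01. Id2 in common lymphoid progenitor-like cells, log2 KO over WT, was -0.63, and -0.38 at 1000 genes, -1.22 thinned and -1.04 as a mean over cells. Genes past the rule in ILC2-like cells, 8 higher and 5 lower, were 26 and 23 with at least 10 UMIs and no CPM minimum, with 20 lower under the marker gate, where 7 of the 13 genes were shared, and 9 lower in thinned cells, where 8 were shared. At 1000 genes clustered again, 27 were higher in ILC precursor-like (13), 9 higher and 5 lower in plasmacytoid dendritic cell-like (4 and 14), and 13 lower in basophil, mast cell or eosinophil-like cells (46). The ratio for the cycling share of ILC precursor-like cells, KO over WT, was 0.593, but 1.20 without thinning and 3.05 at 1000 genes, and for the cycling share of common lymphoid progenitor-like cells, KO over WT, 0.558, but 0.966 without thinning.

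Signs also turned for single genes and lists. At 1000 genes, log2 ratios in ILC precursor-like cells were 1.74 for Ccl4, 0.95 for Calca and 0.12 for Cox6a2, that of Dntt in ILC2-like cells was 0.21, and medians were 0.0896 for B lineage genes in basophil, mast cell or eosinophil-like cells, and -0.17 for cell cycle and 0.0810 for type 2 effector genes in ILC precursor-like cells. In ILC2-like cells thinning gave -0.29 for Cd3g, -0.0364 for Etv6, and Rnf144a in ILC2-like cells, log2 KO over WT, was -0.0368. The marker gate gave 0.17 for Ccl5, 0.38 for Cd24a, -0.0634 for Cish, -0.30 for Mef2c and -0.13 for type 2 effector genes. Under it Itgb1 in ILC2-like cells, log2 KO over WT, was 0.0399. TMM factors gave 0.0103 for ribosomal proteins in ILC precursor-like cells. Depth limits the thinned shares, which leave out 141 WT and 15 KO ILC2-like and 125 WT and 2 KO ILC precursor-like cells as too shallow.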

Other observations

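All values in this part were chosen after seeing the data.

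Cluster 23 held a population that the report does not name, with 4 of the 7 ILC3 markers higher than in other clusters. Its leading genes included Ccr6, Cd4, Cxcl10 and the class II antigen presentation genes H2-Aa, H2-Eb1, H2-Ab1 and Cd74. It stayed without a name because 4 of its 10 leading genes belonged to the mature B cell list and 1 to the ILC3 list. Cluster 23 was 28 of 9678 cells in WT (0.289%, 0.192 to 0.418) and 380 of 4442 in KO (8.55%, 7.75 to 9.42), and 0.860% against 8.82% among cells with at least 1000 genes. Il23r stood at 29.0 CPM (8 UMIs) in WT and 71.4 CPM in KO cells of the cluster, Ccr6 at 232 and 267 CPM, and Il22 at 10.9 CPM (3 UMIs) and 2.25 CPM (5 UMIs), 4.85-fold lower in KO with an interval of 0.753 to 24.9. Id2 stood at 1329 CPM (1196 to 1472) in the 28 WT cells and at 85.8 CPM (74.1 to 98.9) in the 380 KO cells, 15.5-fold lower (13.0 to 18.5). This cluster has fewer than the 30 WT cells asked for elsewhere, and is mostly of 1 library, so it describes these cells only.

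Clusters 6 and 21, also unnamed, took a larger share of the KO library. Cluster 6, with Maf, Bcl11b, Il17rb, Arg1 and Cxcr6 among its leading genes, had 1 leading gene of the ILC precursor list and 2 of the ILC2 list and was 1.29% of cells in WT and 6.37% in KO, or 3.82% and 6.45% among cells with at least 1000 genes. Its Id2 level was 1374 CPM (1305 to 1445) in WT and 319.9 CPM (295 to 346) in KO. Cluster 21 carried NK genes such as Klra7 and Ccl5 together with the T cell genes Cd3d, Cd3e and Trac. It was 1.01% of cells in WT and 6.28% in KO, or 2.83% and 6.42% at 1000 genes. There Id2 stood at 435 CPM (387 to 487) and 349.9 CPM (322 to 379.7), a 1.24-fold difference.

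Id2 was also lower in KO among barcodes left out of all comparisons, at 380.3 CPM in WT (363 to 398) and 62.9 CPM in KO (51.1 to 76.4) under 500 genes, and at 193 CPM (182 to 205) and 71.4 CPM (65.5 to 77.6) among those over 10% mitochondrial UMIs. The pools differed in sex-linked RNA. Xist, made by females, stood at 1338 CPM in WT and 1024 CPM in KO over all kept cells, a ratio of 0.765, and the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were 1.21, 1.25, 1.23 and 1.24 times the WT level in KO, although by the labels each pool held as many males as females.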
